A study of Homo sapiens with 6 samples.

How the data were processed

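Total RNA from 6 samples labelled SKBR3 had been sequenced, 3 per group, and the groups NoDox and Dox and the replicate numbers were taken from the sample titles. The authors deposited FPKM values, fragments per kilobase of transcript scaled to the mapped total, for 16905 genes, with 2 decimals. Per the submitters' processing notes, HISAT2 2.0.4, Bowtie2 2.2.5, RSEM and DESeq2 are named with the human build hg19; which tool did which step, the annotation and any filter are not given in the sources used here. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made by a sequencing company. Per the file headers, the table also held the authors' log2 ratio of Dox to NoDox with its p-value and q-value. Those columns were used only for the comparison with the authors' deposited table and for the estimate of depth.

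Gene IDs were Entrez IDs, of which 16862 matched a symbol in the reference gene tables and 43 did not. No gene was at 0 in all 6 libraries. No listed mitochondrially encoded gene was matched, so 1 of 43 fixed lists was not tested. The FPKM sums ran from 453913 to 466603 per library. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.996 to 0.997 within groups and 0.989 to 0.991 between groups.

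The depth was estimated, since the table gave no fragment totals. After removal of 1 constant, 72% of the authors' log2 ratios among 3476 low genes matched, within 6e-10, a ratio of whole-number group sums of at most 200 for NoDox and 400 for Dox, against 0% after a small random shift of each. Dividing the recovered sums by FPKM and the length of the longest GENCODE release 29 transcript gave a most frequent value of 17500000 fragments per library over 4561 genes. By this estimate a 2 kb transcript at the filter of 0.5 FPKM rests on about 17 fragments per library. The constant gives the ratio of the groups' totals only, as 1.003, so differences in depth within a group are unknown.

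Tests used log2(FPKM + 0.5) for genes with a mean of at least 0.5 FPKM over the 6 libraries, 12058 in all. Count models were not used because the table holds no counts. Linear models were fitted in limma 3.58.1 (R 4.3.3) without covariates, with a mean-variance trend and robust moderation, and the Benjamini-Hochberg adjusted p threshold was 0.05. A set of 43 gene lists was fixed before the data were examined, and those with at least 5 measured members were tested by limma's camera with a preset correlation of 0.01, adjusted over the 42 lists tested. The same was done with an estimated correlation and with fry. For NTN4 a two-sided exact permutation test was added. The self-test simulated Dox against NoDox over 12058 genes with 50 genes changed at each fold: 33, 45, 48 and 49 were called at folds of 1.25, 1.5, 2 and 3, with 15 of 11858 unchanged genes called. Its noise was normal, independent between genes and set by limma's own fitted variances. The counts thus hold for data that meet the model, and are not error rates for these libraries.

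Genes were named by a rule fixed before the data were examined. It took NTN4, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, and up to 4 members with the smallest p from each list past the threshold and from the lists of netrins, laminins, NTN4 neighbours, ERBB receptors and luminal genes. Some genes that the rule selects are not reported here. The genes that mark the labelled line, and VIM and FN1, were singled out after their values were seen. Means are given with SD over 3 libraries unless another n is stated.

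Alternatives covered the pseudocount (0.1 or 1), the filter (none, or a mean of 2 FPKM), scaling (median-ratio, quantile, rescaling to TPM), the replicate number as a block, the variance model, array weights, a 2-fold threshold and leaving out each library. Near-identical copies were searched with blastn 2.17.0 in GENCODE release 29 transcripts at 98% identity. Neighbouring genes were taken from the RefSeq gene table of assembly GRCh38.p14, which is not the authors' build, so no coordinates are given, and their strand from GENCODE. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 was used for the remaining steps.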

Results

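RNA sequencing had been run on cells labelled SKBR3, a breast cancer line known for amplification of the receptor gene ERBB2. The cells carried dCas9-VP64-MPH, a catalytically inactive Cas9 with transcriptional activators, and a guide RNA. Per the labels, 3 libraries came from untreated cells (NoDox) and 3 from cells given doxycycline for 3 days to switch on endogenous NTN4 (Dox). The dose was annotated per sample as 50 ng/mL, while the treatment text gave the same figure per microlitre, so the dose itself is uncertain. The deposited table held FPKM values for 16905 genes, with 11239 to 11287 genes at 1 FPKM or more in each library. Fragment totals were not given, and steps in the deposited ratios placed them near 17500000 per library, so that a 2 kb transcript at 1 FPKM would rest on about 35 fragments. Nothing in the labels says whether the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

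Several genes that mark the labelled line were low in all 6 libraries. ERBB2 stood at 20.1 ± 1.22 FPKM (SD, n = 6), between the 76.1 and 79.4 percentiles of the genes in each library, and GRB7, its neighbour in the amplified segment, at 0.122 ± 0.0731 FPKM. Of 10 listed genes of that segment in the table, 5 averaged 10 FPKM or more, the highest being MIEN1 at 32.3 FPKM. The epithelial adhesion gene EPCAM did not exceed 0.03 FPKM in any library, and the luminal keratin KRT19 averaged 0.168 FPKM. The keratins KRT8 and KRT18 were abundant, at 405 and 308 FPKM, as were the mesenchymal genes VIM (2158 ± 183 FPKM) and FN1 (378 ± 27.6 FPKM). Of 22 luminal genes in the table, 4 reached 10 FPKM. Each direction given for these cells is therefore that of cells labelled SKBR3.

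**Figure D1:**
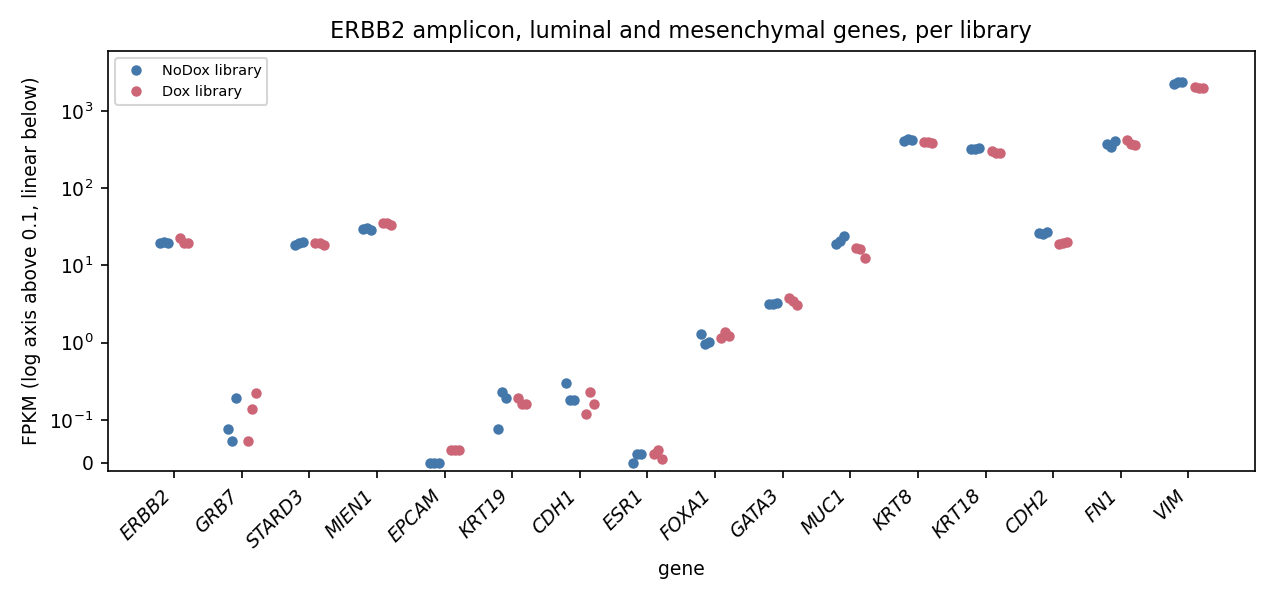
FPKM of ERBB2 amplicon, luminal and mesenchymal genes in each library (points; NoDox blue, Dox red), on an axis that is logarithmic above 0.1 and linear below. ERBB2 averaged 20.1 FPKM over the 6 libraries, EPCAM stayed at or below 0.03 and VIM averaged 2158.

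The first comparison asked whether doxycycline raised NTN4, the gene of the secreted laminin-related protein netrin-4. NTN4 (Entrez gene 59277, chromosome 12) rose from 4.04 ± 0.247 FPKM in NoDox to 998 ± 8.26 FPKM in Dox (SD, n = 3 each), a 247-fold difference of means. All 3 Dox libraries lay above all 3 NoDox libraries. In limma on log2(FPKM + 0.5) the change was 7.78 (95% confidence interval 7.68 to 7.89, adjusted p = 2.42e-17), a scale that understates the change of low genes. The two-sided exact permutation test gave p = 0.1, the smallest p that 3 libraries against 3 allow.

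Across the genome the second comparison asked which other genes differed between Dox and NoDox. By log2 change the largest rises after NTN4, apart from SERF1A (4.43, uncertain as described below), were in AVPI1, a vasopressin-induced gene, from 5.17 ± 0.708 to 99.6 ± 2.6 FPKM, and in LCN1, which encodes tear lipocalin, from 0.557 ± 0.122 to 17.7 ± 3.08 FPKM (SD, n = 3). The hormone-sensitive lipase gene LIPE was at 0.04 FPKM or less in NoDox and at 5.96 ± 0.332 FPKM in Dox. EMILIN2, an extracellular matrix glycoprotein gene, rose from 3.79 ± 0.123 to 52 ± 2.07 FPKM, a 13.7-fold difference of means. RHOV (log2 change 3.17), FETUB (2.94) and CHI3L1 (2.90) followed, and adjusted p for the risers named here was at most 7.06e-10.

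The largest falls were smaller than the rises. SLAMF9, a gene of the SLAM receptor family, fell from 7.97 ± 1.54 to 1.84 ± 0.496 FPKM (log2 change -1.87, limma adjusted p = 1.07e-04). The hypoxia-induced carbonic anhydrase gene CA9 fell from 26.5 ± 4.25 to 11.1 ± 2.57 FPKM, and the gelatinase gene MMP9 from 20.7 ± 2.55 to 8.79 ± 1.83 FPKM. The basal keratin KRT15 (-1.03) and PLAT, the tissue plasminogen activator gene (-1.01), also fell by about 1 on the log2 scale. NDRG1, a stress-induced gene, fell from 838 ± 72.4 to 391 ± 83.8 FPKM (limma adjusted p = 0.0114). Its call ended without NoDox replicate 2 (adjusted p = 0.0572), NoDox replicate 3 (0.0504) or Dox replicate 3 (0.0534), and adjusted p ranged from 2.35e-06 to 0.0572 over 16 alternatives.

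Of the genes with the largest changes, 3 are uncertain because their reads can belong to another gene. SERF1A was listed at 0 in all 3 NoDox libraries and at 9.4 to 12 FPKM in Dox. Its near-identical copy SERF1B went the other way, from 13.8 to 5.71 FPKM on average. NME1-NME2, a read-through of neighbouring genes (log2 change -1.40, lost without Dox replicate 2 at adjusted p = 0.054, range 1.78e-06 to 0.054 over 16 alternatives), and FAM72D, one of several close paralogs (-1.01), are uncertain for the same reason.

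**Figure D2:**
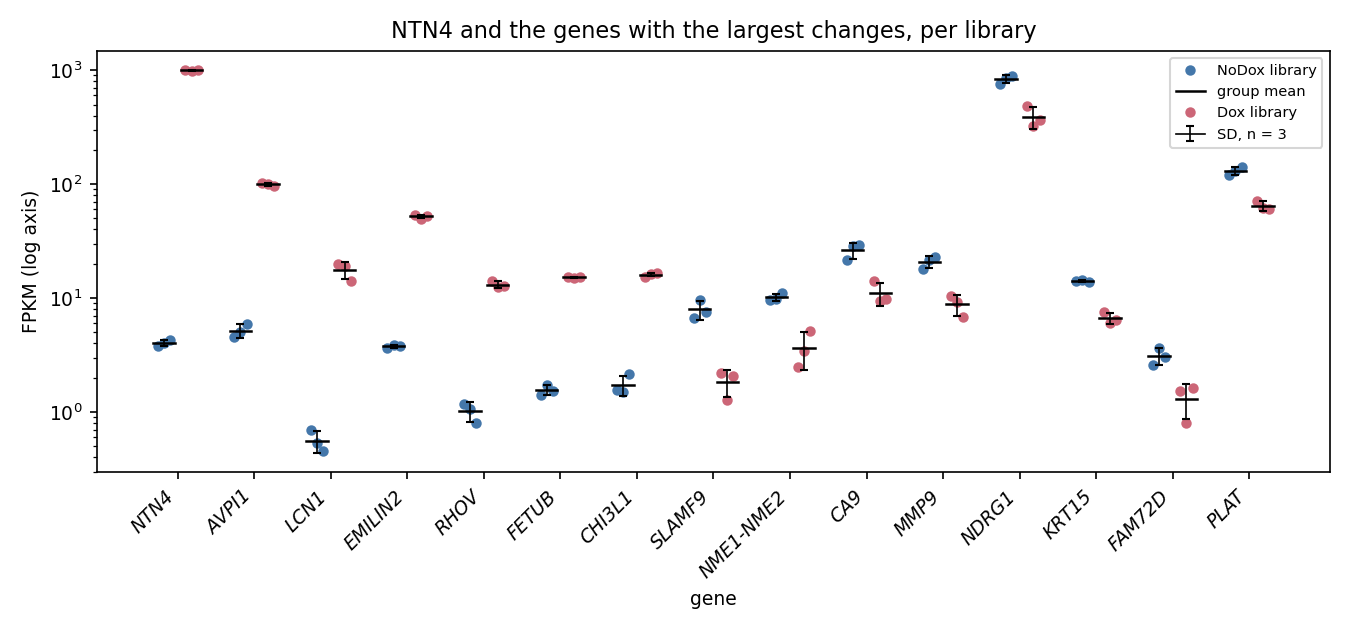
FPKM per library (points; NoDox blue, Dox red) on a log axis for NTN4 and the genes with the largest changes, with group means (horizontal lines) and SD (n = 3). NTN4 went from a mean of 4.04 to 998 FPKM and SLAMF9 from 7.97 to 1.84; SERF1A and LIPE, which hold values of 0, are not drawn.

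In total, limma with Benjamini-Hochberg adjustment called 2052 of 12058 tested genes (17%), of which 1132 were higher and 920 lower in Dox. A change of 2-fold or more was met by 66 of them, 58 higher and 8 lower. At an unadjusted p under 0.05 there were 3786 genes, and in 4176 genes (34.6%) the groups did not overlap, against 10% by chance. With quantile normalization 902 genes were higher and 1122 lower, with median-ratio scaling 949 and 1035, and after rescaling to TPM 939 and 1065. Each of these scalings turned the excess of higher genes into one of lower genes, so the balance of directions among small changes was not fixed. The total dropped to 1128 without NoDox replicate 2 and to 1231 without Dox replicate 2.

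Most measured genes induced by low oxygen fell. Of 27 measured hypoxia response genes, 20 fell and 1 rose (21 and 1 adjusted over the list alone). VEGFA, the angiogenic growth factor gene, fell from 46.5 ± 3.36 to 27.5 ± 0.411 FPKM, CA12 from 9.28 ± 0.285 to 4.64 ± 0.284, and BNIP3, a mitophagy gene, from 232 ± 14.3 to 151 ± 8.74 FPKM (SD, n = 3). Of 24 glycolysis genes, 17 fell and 0 rose (18 and 0 adjusted over the list alone), among them the glucose transporter gene SLC2A1 (log2 change -0.73), ENO2 (-0.86), HK2 (-0.53) and LDHA, which went from 1452 ± 23.7 to 1133 ± 41.8 FPKM. By limma's camera, adjusted p was 3.84e-15 for the hypoxia list and 3.25e-14 for glycolysis, and adjusted p = 0.271 for both with an estimated correlation. Of 20 angiogenic factor genes, 7 fell and 2 rose (8 and 2 adjusted over the list alone), with EFNB2 (-0.42) and VEGFC (-0.35) among those that fell and ANGPT2 (0.89) rising. That list had a camera adjusted p = 0.0128, and lost its call with an estimated correlation (adjusted p = 0.431) and with no filter on low values (0.057).

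Among cell cycle genes more fell than rose, by small amounts. Of 52 genes of G2 and mitosis, 28 fell and 0 rose (38 and 1 adjusted over the list alone), including HJURP, a centromere chaperone gene, from 31.3 ± 0.596 to 24.1 ± 0.89 FPKM, UBE2C (log2 change -0.27), PBK (-0.32) and KIF20A (-0.26). Of 47 S phase genes, 9 fell and 0 rose (14 and 0 adjusted over the list alone), E2F8 by the most among those named (-0.49). Camera adjusted p was 3.84e-15 and 1.51e-06, with adjusted p = 0.314 and adjusted p = 0.441 with an estimated correlation. Of 15 replication-dependent histone genes, 6 rose and 1 fell (7 and 2 adjusted over the list alone), among them H2BC21 (0.64) and H2BC12 (0.28), both from a family of close relatives, so that their values are uncertain. The 33 histone genes in the table were mostly low, with a median of 0.395 FPKM and 4 at 10 FPKM or more. The histone list had a camera adjusted p = 0.0392, and adjusted p = 0.271 with an estimated correlation. It lost its call in 6 of 18 alternatives, among them those without Dox replicate 1 (0.101) and Dox replicate 3 (0.0688).

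In the lists of mitochondrial respiration, sterol synthesis and lysosomes more genes rose than fell. Of 74 nuclear-encoded respiratory chain genes, 21 rose and 1 fell (26 and 1 adjusted over the list alone). COX6B1, a cytochrome c oxidase subunit gene, rose from 248 ± 11.4 to 402 ± 29.6 FPKM and NDUFB10 rose by 0.25 on the log2 scale, while UQCRFS1 fell (-0.44). Of 75 mitochondrial ribosome genes, 9 rose and 2 fell, with the same counts adjusted over the list alone, MRPL36 being higher (0.19). The median change of the mitochondrial ribosome genes was only 0.066. Over all 12058 tested genes 1132 rose and 920 fell. Of 25 cholesterol synthesis genes, 15 rose and 0 fell (16 and 0 adjusted over the list alone), among them ACAT2, from 31.7 ± 0.867 to 49 ± 3.8 FPKM, the squalene synthase gene FDFT1 (0.37) and MVD (0.39). Of 28 lysosome and autophagy genes, 8 rose and 0 fell (11 and 0 adjusted over the list alone), including the cathepsin B gene CTSB (0.35) and the autophagy receptor gene SQSTM1 (0.29). In the order named, camera adjusted p was 1.85e-06, 0.0128, 1.01e-05 and 1.88e-04, and with an estimated correlation adjusted p = 0.441, 0.613, 0.271 and 0.271. The mitochondrial ribosome list lost its call in 4 of 18 alternatives, among them that without Dox replicate 2 (0.0667).

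**Figure D3:**
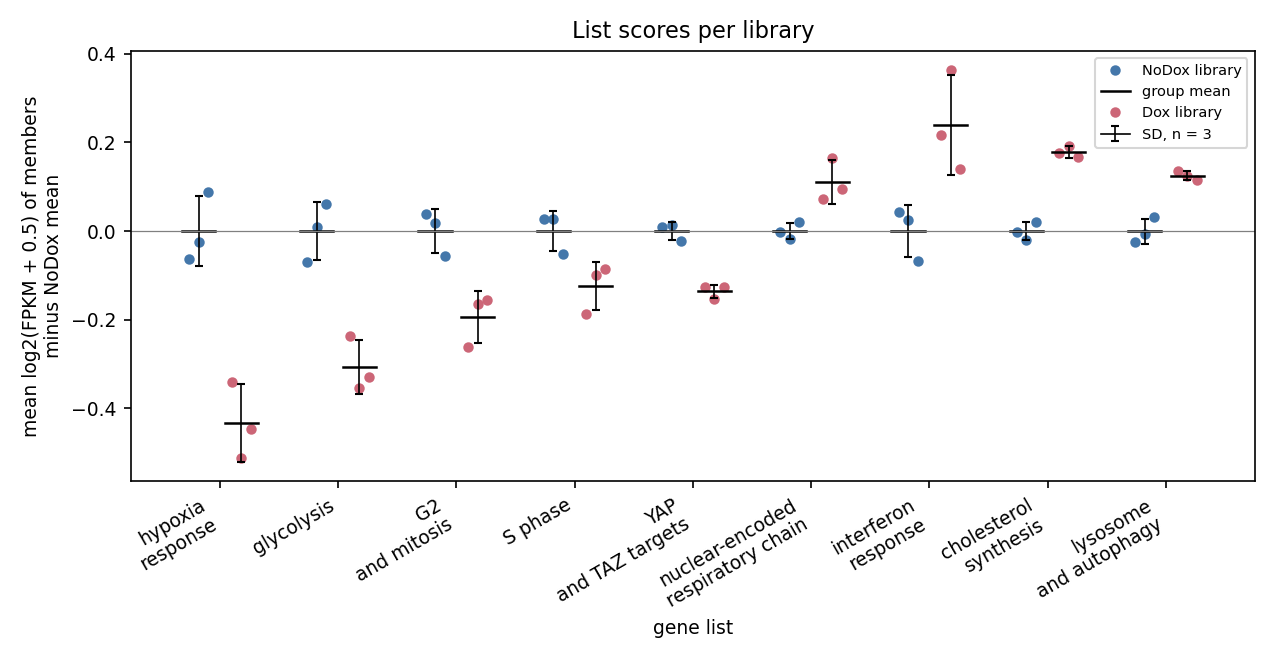
Mean log2(FPKM + 0.5) of the measured members of 9 lists, per library, minus the NoDox mean (points; NoDox blue, Dox red), with group means (horizontal lines) and SD (n = 3). Hypoxia scores lay between -0.063 and 0.088 in NoDox and between -0.51 and -0.34 in Dox.

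Among interferon response genes more rose than fell, and stress lists were mixed. Of 42 interferon response genes, 18 rose and 1 fell (21 and 1 adjusted over the list alone). The ubiquitin-like modifier gene ISG15 rose from 21.8 ± 3.28 to 43 ± 5.73 FPKM, IFI27 from 6.95 ± 0.481 to 12 ± 2.24 and IFITM1 from 17.6 ± 1.78 to 28.8 ± 4.16 FPKM. Of 27 NF-kB and cytokine genes, 7 fell and 3 rose (10 and 3 adjusted over the list alone), with TRAF1 (log2 change -0.68) falling and IL1B (0.76) rising. Of 38 integrated stress response genes, 12 fell and 6 rose (15 and 7 adjusted over the list alone): the amino acid transporter gene SLC7A5 (-0.55) and STC2 (-0.70) fell, while the proline synthesis gene PYCR1 (2.08) and CEBPB (0.83) rose. Of 6 genes for metallothioneins and the metal response, 4 fell and 0 rose (4 and 1 adjusted over the list alone), MT1X from 152 ± 11.8 to 95.7 ± 14 FPKM, uncertain because its family holds close relatives. In the order named, camera adjusted p was 4.11e-06, 0.0392, 0.0157 and 0.0231, and with an estimated correlation adjusted p = 0.441, 0.625, 0.271 and 0.271. The metallothionein list also lost its call with no filter on low values (0.0726) and with no trend and no robust moderation (0.0723). The NF-kB list lost its call in 10 of 18 alternatives, among them those without NoDox replicate 2 (0.0522), NoDox replicate 3 (0.216), Dox replicate 2 (0.0857) and Dox replicate 3 (0.122).

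Genes of adhesion and of the netrin and laminin families moved apart. NTN5, another netrin gene, rose from 0.06 ± 0.03 to 3.17 ± 0.325 FPKM, and the adhesion receptor gene MCAM fell (log2 change -0.24), so that with NTN4, 2 of 8 netrin and netrin receptor genes rose and 1 fell (2 and 1 adjusted over the list alone). Of 18 laminin and basement membrane genes, 4 rose and 4 fell (6 and 5 adjusted over the list alone): LAMC1, the laminin gamma 1 gene, went from 62.2 ± 3.24 to 101 ± 2.35 FPKM, AGRN (0.57) and LAMA5 (0.49) also rose, and LAMA4 (-0.36) fell. ITGB1, the integrin beta 1 gene, rose from 345 ± 10.2 to 785 ± 28.1 FPKM, yet 4 of 14 integrin genes fell and 1 rose (5 and 1 adjusted over the list alone), ITGB3 (-0.67) and ITGA6 (-0.30) among those that fell. Camera adjusted p was 0.0104 for integrins, with adjusted p = 0.417 with an estimated correlation, and the netrin (0.0863) and laminin (0.73) lists did not pass, although the netrin list did by fry (2.8e-06), with quantile normalization (0.0453) and after rescaling to TPM (0.0482). That list holds NTN4, the gene switched on by design, and its mean change of 1.29 against a median of 0.038 rests on NTN4 and NTN5, so its passing says little about the other members. Of 9 genes near NTN4 on chromosome 12, 2 fell and 0 rose (2 and 1 adjusted over the list alone), ELK3 (-0.17) and VEZT (-0.21), and that list did not pass (0.0863), although it did without NoDox replicate 3 (0.0299). Both calls were fragile: ELK3 lost its call in 5 and VEZT in 6 of 16 alternatives.

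Some targets of several signalling pathways changed. Of 22 YAP and TAZ target genes, 11 fell and 2 rose (13 and 3 adjusted over the list alone), including the receptor tyrosine kinase gene AXL, from 120 ± 1.96 to 93.4 ± 2.6 FPKM, MYOF (log2 change -0.39) and the tissue factor gene F3 (-0.46). Of 9 WNT targets, 4 fell and 0 rose, also adjusted over the list alone: CD44 (-0.35), CCND1 (-0.25), MYC (-0.32) and EPHB2 (-0.28). Of 9 NOTCH targets, 4 rose and 0 fell, also adjusted over the list alone: HES1, from 2.45 ± 0.375 to 7.35 ± 0.731 FPKM, JAG1 (0.59), HES4 (0.66) and NOTCH1 (0.62). Of 8 kidney and embryonic line markers, listed as signs of other cells, 4 fell and 1 rose (4 and 1 adjusted over the list alone), including CDH2 (-0.42) and NEFL (-0.29). In the order named, camera adjusted p was 1.22e-04, 0.00526, 0.0387 and 0.0104, and with an estimated correlation adjusted p = 0.271, 0.271, 0.613 and 0.271. The NOTCH list lost its call in 4 of 18 alternatives, among them that without Dox replicate 1 (0.0756).

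Genes tied to ERBB signalling and the luminal lineage moved singly. SPRY4, a feedback inhibitor gene of receptor signalling, rose from 28.1 ± 1.11 to 79 ± 1.73 FPKM, the receptor gene ERBB3 rose from 1.55 ± 0.266 to 3.5 ± 0.632 FPKM, and the ligand genes TGFA (log2 change -0.61) and HBEGF (-0.26) fell. Of 18 ERBB receptor and ligand genes, 3 rose and 4 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.314). Of 10 luminal genes, 1 rose and 2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.558). In both lists the median change was below 0 (-0.12 and -0.058) and the mean above it (0.043 and 0.029). The ERBB median shrank to -0.0016 without NoDox replicate 3 and the luminal median to -0.032 without Dox replicate 2. Markers of leukocytes, fibroblasts and endothelium gave 0, 1 and 1 genes higher and 0, 1 and 1 lower among 5 measured in each.

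**Figure D4:**
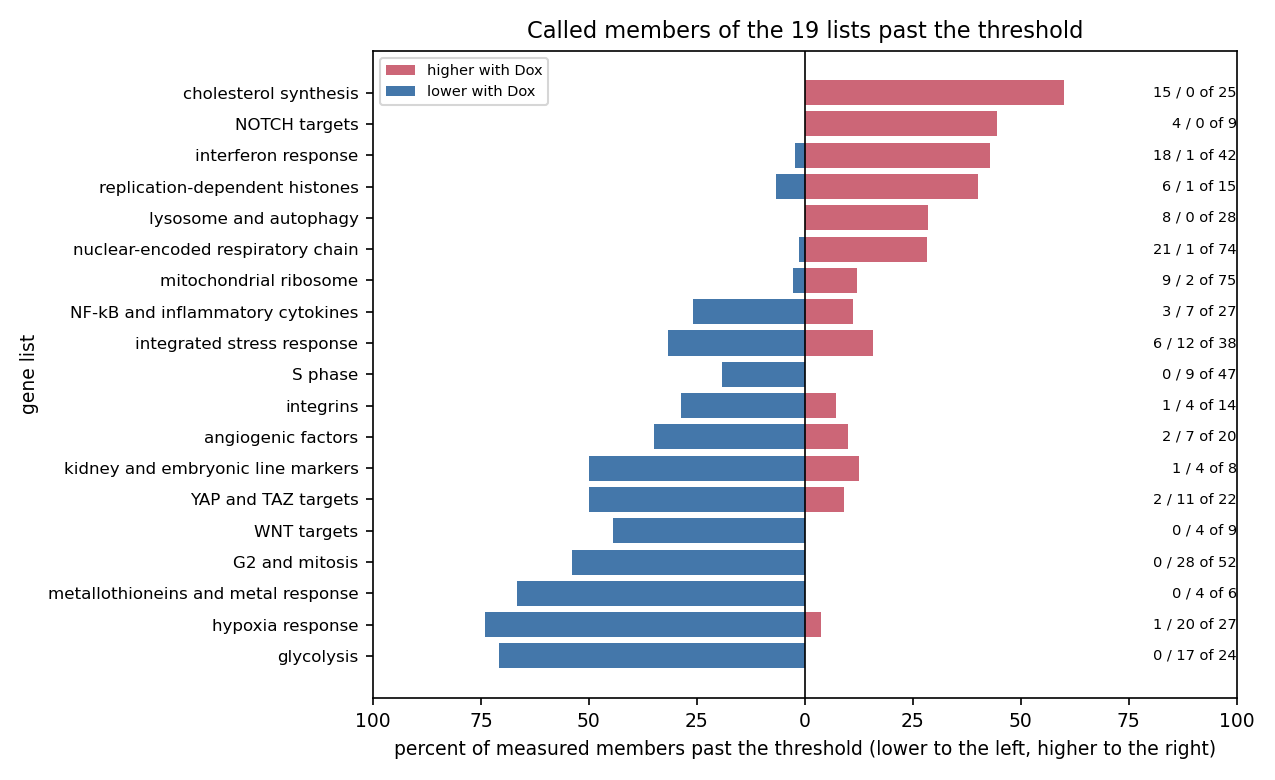
Percent of measured members called by limma as higher (red, right) or lower (blue, left) in Dox for the 19 lists past the camera threshold, with the counts at the right margin. Hypoxia response had 1 higher and 20 lower of 27, cholesterol synthesis 15 higher and 0 lower of 25.

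Over all lists, camera with its preset correlation placed 19 of 42 past the threshold, 7 higher and 12 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.271 and 6 lists had an unadjusted p under 0.05. Lists whose estimated correlation lay below the preset 0.01 lost their calls too, such as WNT targets (-0.0577) and metallothioneins (-0.127), both at camera adjusted p = 0.271. For such lists the loss cannot come from a higher correlation, so losing the call does not show that a list's genes are correlated. By fry, which asks whether a list's genes move one way on balance, 18 passed, 14 of them shared with camera. The 5 that passed camera only were S phase (fry adjusted p = 0.0624), interferon response (0.0582), integrins (0.233), mitochondrial ribosome (0.117) and NF-kB (0.144), and the 4 that passed fry only were netrins, fatty acid synthesis, FOXO targets and basal epithelium. The other 23 lists had adjusted p from 0.0863 to 0.814. Another split of the 6 libraries gave 18 lists by camera, while no other split called more than 2 genes. Every other split mixes Dox and NoDox libraries within each group, so the treatment difference widens the spread there. Their low gene counts are therefore no chance level for the 2052 genes. For 11 of the 19 called lists another split gave a camera p as small or smaller, with S phase, interferon response, the respiratory chain and integrins among them.

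The authors' deposited table also held its own comparison, with a log2 ratio for 15912 genes. The test behind its p-values is not stated. Of 342 sets of genes that share both ratio and p-value, 117 hold genes above 0 in different numbers of libraries, so for these the p-value did not follow the spread over libraries. Whether that holds for the other genes is unknown, and the count of genes may not mean what that of limma does. In the authors' deposited table, 6042 genes had q under 0.05, 3383 higher and 2659 lower in Dox, and NTN4 had a log2 ratio of 7.95. With an absolute log2 ratio of 1 or more as well there were 309, 203 higher and 106 lower, a less uneven split than the 58 and 8 of limma. Of the 2052 genes called by limma, 2042 had q under 0.05 and the same sign in the authors' deposited table. The reverse held for 2042 of the 5707 tested genes that the authors' deposited table called.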

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

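All alternatives were chosen before the data were examined. NTN4 kept its call and direction in the 16 in which it was fitted, which leave out the 2-fold threshold, with a log2 change between 7.63 and 7.92. Over 111 named genes and their alternatives, 1702 of 1773 values kept direction and side of the threshold, 66 lost the call, 5 gained one and 0 changed sign. Of 431 values for 24 lists, 379 did, 45 lost the call and 4 gained one. Most named genes and lists were picked for their changes in these same libraries, so most were likely to keep their calls. For the lists of ERBB receptors and luminal genes the sign under fry was opposite to the median (-0.12 and -0.058), while the means lay above 0. The ERBB median shrank to -0.0016 without NoDox replicate 3, and the luminal median to -0.032 without Dox replicate 2 and -0.013 with no filter. The laminin list's camera direction turned without Dox replicate 1 (median 0.0605); its median without 1 library ranged from 0.019 to 0.064. With an estimated correlation 0 lists passed, and 9 of the 19 lists lost the call in at least 1 other alternative.

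The number of called genes depended on the variance model more than on scaling. Array weights gave 3259 genes, 1879 of them higher, and a 2-fold threshold gave 66, 58 higher and 8 lower, since it removes small changes. Leaving out a library gave 1128 to 1966 genes, 603 to 1105 higher and 525 to 861 lower, with fewer libraries in the fit. The smallest counts came without NoDox replicate 2 (1128) and without Dox replicate 2 (1231). Between 1101 and 1674 of the 2052 genes were called again, with 0 sign changes. These fits reuse the remaining libraries, so they are no independent repeat. Quantile normalization moved the split to 902 higher and 1122 lower, although the median over all genes shifted by little, from 0.0137 to -0.0046. Median-ratio scaling (949 higher and 1035 lower) and rescaling to TPM (939 and 1065) reversed the balance as well. The cause of these movements was not tested further.

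Same-numbered libraries did not deviate together (correlations -0.203, -0.115 and -0.261 across genes), so the values gave no sign of pairing by number. This cannot show whether the samples were prepared in pairs. The fit with the replicate number as a block gave 1250 genes, 667 higher and 583 lower, and ended the calls of 13 named genes. Among them were CA9 (limma adjusted p = 0.0827, range 5.1e-05 to 0.0827 over 16 alternatives) and MRPL36 (0.0618, range 0.00625 to 0.0618). The planned count model was not run because the table holds no counts. With no filter, 1531 genes were called of 16905, and the cause of the lower count was not tested.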

Other observations

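The genes named in this and the next paragraph were chosen after their values were seen. Chaperone genes moved apart: DNAJB1, a co-chaperone of HSP70, rose from 53.1 ± 1.31 to 194 ± 4.07 FPKM (log2 change 1.86) and HSPA6, which shares sequence with close relatives, by 1.03 on the log2 scale, while HSP90AA1 (-0.26), HSP90AB1 (-0.24) and HSPD1 (-0.22) fell. Over the 27 heat shock protein genes 3 rose and 4 fell (3 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.286). Of 19 fatty acid synthesis genes 4 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.277), with FASN, the fatty acid synthase gene, going from 49.7 ± 2.62 to 75.5 ± 4.72 FPKM, and SCD (0.35) and SREBF1 (0.40) higher.

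Mesenchymal and growth-response genes were also split. The stromelysin gene MMP3 rose from 0.99 ± 0.296 to 6.64 ± 0.426 FPKM and the transcription factor gene SNAI1 from 5.55 ± 0.345 to 13.8 ± 1.23 FPKM, while the collagen crosslinking enzyme gene LOX (log2 change -0.69) and VIM (-0.21) fell. Of 18 mesenchymal genes 5 rose and 4 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.73). EGR1 rose from 1.23 ± 0.0854 to 4.27 ± 0.552 FPKM, with JUND (0.71) and JUNB (0.57) higher and DUSP1 (-0.48) lower. Of 23 immediate early genes 4 rose and 5 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.73).

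Tests of line identity, of lost ERBB2 reads, of mitochondrial translation and of the share of risers among abundant genes, and the comparison with neighbours of smaller risers, were chosen only after the result was seen. The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 2052 genes, and the highest other gave 2. Since the other splits mix Dox and NoDox libraries within each group, the treatment difference widens their spread, and their low gene counts show no chance level. Higher genes numbered 1132 and lower genes 920 in the real split, against at most 1 in one direction in the others, and called lists numbered 19 against at most 18. In each of these 4 counts, 1 of the 10 splits, the real one, gave a result as large. The camera p of 8 of the 19 called lists, hypoxia, glycolysis, mitosis and cholesterol synthesis among them, was the smallest of the 10 splits. For the other 11 another split gave an unadjusted camera p as small or smaller. Among them were interferon response (1.22e-12 against 5.87e-07 in the real split) and the respiratory chain (5.08e-11 against 2.2e-07). Integrins (9.8e-07 against 0.00293) and NF-kB (7.03e-07 against 0.0168) were too.

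Low ERBB2 and luminal genes in libraries labelled SKBR3 were weighed against 2 explanations. A loss of ERBB2 reads alone in mapping or counting is argued against, since GRB7 was at 0.122 FPKM and only 18.2% of the luminal genes in the table reached 10 FPKM. GRB7 does not stand for the whole amplified segment, as 5 of its 10 listed genes in the table averaged 10 FPKM or more. The highest of them, MIEN1, averaged 32.3 FPKM and stood at or below the 86.3 percentile in every library. These levels do not show that the segment was amplified in these cells. Whether the cells are of another line than the label names stays open. ERBB2 stood at or below the 79.4 percentile, EPCAM at or below 0.03 FPKM and KRT19 at or below 0.23 FPKM in every library. KRT8 and KRT18 were abundant. The low levels argue against cells that kept the marker expression of the labelled line. They also raised the question, and cannot tell another line from a changed one. A derivative of the labelled line that lost these features also stays open, as does a mix-up at any step, and no biological explanation was tested.

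Lower hypoxia, glycolysis and mitosis genes in Dox were weighed next. Scaling between libraries is argued against, since the hypoxia median stayed at -0.47 or lower under 3 other scalings. An action of doxycycline on mitochondrial translation cannot be told apart from other effects of the treatment: 66.7% of the called integrated stress response genes were lower, but members went both ways, and the groups' scores lay 0.0058 apart against ranges of 0.0431 and 0.0504 within groups. Culture conditions that differed between the groups, such as cell density, cannot be told apart from the treatment: the gap between the groups' hypoxia scores was 1.6 times the larger range within a group, which a difference in handling by group could also give. For glycolysis the gap was 0.168 against a larger range of 0.131. For G2 and mitosis it was 0.0991 against 0.106, so there the gap was smaller than the range within Dox. An effect of NTN4 stays open and untested, because none of the 6 libraries came from cells given doxycycline without the guide.

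Genes that rose by 2-fold or more numbered 58 and those that fell 8. In the authors' deposited table, which covers more genes on another scale, 203 rose and 106 fell at q under 0.05 and an absolute log2 ratio of 1 or more. Too few fragments are argued against: at a mean of 10 FPKM or more over the 6 libraries 22 rose and 5 fell (81.5% risers), with 85.5%, 85.4% and 88.2% risers at 2, 5 and 20 FPKM, while the planned test, that risers reach 2 FPKM in every Dox library (89.7%), was set aside because risers are picked for being high in Dox. Near-identical copies are argued against too, since 6.9% of the risers had one (HSPA6, SERF1A, STBD1 and PLSCR3) against 7.61% of random genes and 25% of the fallers (2 of 8). Activator binding near other genes may contribute: 18.2% of the 110 immediate neighbours of risers also rose (7 of these 20 downstream on the same strand), CA11 beside NTN5 and EML3 and B3GAT3 beside ROM1 among them, against a median of 8.62% over 10000 draws matched on expression (one-sided permutation p = 9e-04). Of the 20 risen neighbours, 2 overlapped the riser. Near NTN4, the intended target, 0 of 9 measured genes rose and 2 fell. Neighbours of genes that rose by less also rose in 14.4% of cases, and against draws from those the one-sided permutation p was 0.0719. Activator binding thus cannot be told apart from neighbours that rise together for other reasons.

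In the authors' deposited table, 2021 genes shared both their log2 ratio and their p-value with at least 1 other gene, in 342 sets, and 117 of these sets held genes above 0 in different numbers of libraries.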
